A study of Mus musculus with 12 samples.

How the data were processed

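Gene expression was measured in 6 cultures of mouse bone marrow-derived mast cells, 3 of precursors and 3 of mature cells, each on 1 Affymetrix MOE430A and 1 MOE430B array, so that the culture was the replicate. The deposited values are intensity per probe set on a linear scale. Per the labels, the authors made them with MAS5, whose version and settings are not stated. The values themselves show that each array had been scaled so that its mean without the top and bottom 2% of probe sets was about 1500. No detection calls were used. The other deposited files, the instrument records of the arrays (unit: other, not a measurement), were read for chip lot, fluidics station and scan day only.

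The 2 chips were handled apart. Values below the 30th percentile of a chip's table (247 on chip A, 359 on chip B) were set to that floor, and log2 values were taken. Probe sets were kept when at least 3 of 6 arrays lay above the table's median (582 on chip A, 864 on chip B), and control sets were left out. This left 11576 of 22626 probe sets on chip A and 11880 of 22511 on chip B. Of the probe sets on chip A, 20380 carried 1 gene symbol, 691 several and 1555 none, and on chip B 14661, 245 and 7605. Mature and precursor cultures were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend and no covariate. P-values were adjusted by Benjamini-Hochberg within a chip, and an adjusted p under 0.05 was called changed. Differences are mature minus precursor, tests are two-sided, SDs are among the 3 cultures of a group, and SEs come from the fit. A fold against a group at the floor in all 3 cultures was taken against the floor and is a lower bound. A rank test of 3 against 3 cannot give an exact p under 0.1, so none was used.

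Gene lists on mast cell functions, progenitors, other cell types and cell processes were tested with limma camera on chip A, with an inter-gene correlation of 0.01 and the brightest probe set per gene. Lists with at least 5 measured genes on chip A entered, 28 in all, and p-values were adjusted over them. Members were counted over both chips, with chip A first for a gene on both, over all genes tested and again adjusted over the list alone. An estimated correlation, fry and chip B were run beside this. fry asks whether a list's genes move on balance one way and does not compare them with other genes.

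The cultures, the tests, the gene lists, the main alternatives and the rule for named genes were set before the data were examined. The rule took, among changed sets with 1 gene symbol that is not a clone or predicted-gene name and with no overlap between the groups, up to 10 rises and 10 falls on chip A and 5 and 5 on chip B, with the largest log2 difference. It also took 12 fixed mast cell genes, up to 3 rises and 3 falls per list or the 2 brightest members where fewer than 2 passed, and 5 sex-linked genes. Other list members, such as Csf1r, Clec7a, Cd68, Adgre1 and Ctsz and the genes past the test adjusted over the list alone, were named after their values were seen.

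The alternatives were other scalings, floors, filters, thresholds and adjustments, sex, fluidics station or labelling batch as a block, no intensity trend, array quality weights, and each culture left out in turn. The interaction of stage and sex was fitted with limma and camera after the results by sex were seen. On simulated data with 200 changed probe sets, the chip A fit recovered 0 at a log2 change of 1, 143 at 2 and 184 at 3, with 0, 8 and 12 false calls, and the chip B fit recovered 0, 114 and 156, with 0, 9 and 11 false calls. The list test called 3 of 200 unchanged simulated lists at an unadjusted p under 0.05 and 50 of 50 lists shifted by a log2 of 1. The simulated noise was independent between probe sets. These counts therefore do not give the error rate for lists of correlated genes, such as mitosis (estimated correlation 0.731).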

Results

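The cells were mast cells grown from mouse bone marrow in medium with interleukin-3 (IL-3), a growth factor for mast cells and other myeloid cells. The labels divide 6 cultures into 3 cultures of mast cell precursors, taken after 14 to 16 days (M1, M3 and M5), and 3 cultures of mature mast cells, taken after 57 to 110 days (M2, M4 and M6). M1 and M6 are labelled female and the others male. The labels put purity at about 80% and name stromal cells, monocytes and macrophages as possible other cells. Total RNA of each culture was read on 1 Affymetrix MOE430A array (chip A) and 1 MOE430B array (chip B), 12 arrays in all, and nothing in the labels says more than that the cultures were separate. The median signal was 536 to 695 per array on chip A and 819 to 916 on chip B. The number of arrays limits the precision of every value. The stem cells that the series title names are not analysed here.

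The comparison asked how gene expression differed between mast cell precursors and mature mast cells. The mature cultures had far lower signal of some genes known from macrophages, monocytes and granulocytes, such as Chil3, Lyz2, Csf1r and H2-Aa. Of 14 measured granulocyte markers 12 did not pass, nor did further sets of Csf1r and H2-Aa. Known mast cell genes, such as Kit, Fcer1a and Cpa3, were bright in all 6 cultures and did not pass the test. The granule genes for histidine decarboxylase (Hdc) and cathepsin G (Ctsg) fell. A small group, with Gcsam, Smpx, Hbb-y and Jun, rose. In limma at an adjusted p under 0.05, 61 of 11576 probe sets on chip A changed, 51 lower and 10 higher in the mature cultures. They stood for 43 genes, 36 lower and 7 higher, and 8 of the sets had no single symbol. On chip B, 11 of 11880 probe sets changed, 8 lower and 3 higher. At an unadjusted p under 0.05, 763 sets passed on each chip, against 579 on chip A and 594 on chip B that chance gives. The 2 groups of cultures did not overlap in 1412 sets on chip A (12.2%) and 1426 on chip B (12%), where chance gives 10%. The chip A count was 1 with no filter on dim probe sets, a set that was not among the 61. It was 21 without M5, 25 without M2, and 39 with the labelling batch, inferred from spike controls, as a block. The chip B count was 5 without M2 or M4, 6 without M5 and 3 without M6.

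Among the named genes that fell, Chil3, a chitinase-like protein of macrophages and neutrophils (chromosome 3), had the largest difference. Its log2 signal was 15.27 ± 0.67 (SD, n = 3) in the precursors and lay at the floor in each mature culture, so that it was at least 159.9-fold lower (adjusted p = 2.44e-06, limma). Lyz1, a lysozyme gene (chromosome 10), had a log2 signal of 16.50 ± 0.10 (SD, n = 3) in the precursors and 11.39 ± 1.59 in the mature cultures, a 34.7-fold fall (adjusted p = 0.00464, limma). A further set of Lyz1 fell 25.95-fold, and the other lysozyme gene, Lyz2, fell 13.0-fold. Whether the sets of these 2 genes read each other's RNA was not tested. Ctsg, a serine protease of mast cell and neutrophil granules (chromosome 14), had a log2 signal of 14.39 ± 0.74 in the precursors and 9.40 ± 1.30 in the mature cultures (SD, n = 3), a 31.8-fold fall (adjusted p = 0.00464, limma). H2-Aa, a chain of an MHC class II molecule (chromosome 17), fell 23.0-fold on chip A and 19.9-fold on chip B, while a further chip A set had a difference of -1.05 ± 0.57 (log2, SE) and did not pass. Wfdc17 on chip B (chromosome 11) had a log2 signal of 13.77 ± 0.54 in the precursors and 8.58 ± 0.16 in the mature cultures (SD, n = 3), a 36.5-fold fall (adjusted p = 6.81e-05, limma). Cathepsin S (Ctss) fell 25.7-fold, the matrix protein gene Tgfbi 19.4-fold and the fatty acid binding protein gene Fabp5 9.85-fold. Other sets fell 13.4-fold and 9.20-fold for Tgfbi and 6.15-fold for Fabp5. App, the amyloid precursor protein gene, was at least 13.9-fold lower, Mpeg1, a perforin-like protein of macrophages, at least 10.1-fold lower and Clec4a3, a C-type lectin, at least 13.3-fold lower, each at the floor in the 3 mature cultures. Pxdc1 on chip B fell 4.79-fold. The floor entered the mature mean of Wfdc17 in 2 of the 3 cultures and of Ctsg, Ctss, the 19.4-fold set of Tgfbi and the 23.0-fold set of H2-Aa in 1, so that their folds depend on it. Over the alternatives the log2 difference ran from -8.36 to -6.09 for Chil3, -4.40 to -2.56 for App, -4.67 to -2.10 for Mpeg1, -5.75 to -2.47 for Clec4a3 and -5.40 to -4.02 for Wfdc17. It ran from -5.52 to -4.27 for Ctsg, -5.53 to -3.95 for Ctss, -5.23 to -3.44 for Tgfbi and -5.15 to -3.77 for H2-Aa on chip A. Among the named genes that changed and had no culture of the lower group at the floor, Lyz1 had the widest move, from -5.12 to -6.00. In each of these probe sets, except the further set of H2-Aa, all 3 mature cultures lay below all 3 precursor cultures. The rule for named genes required this of the sets it took. The calls of some of these genes ended when 1 culture was left out: Ctss (without M5 or M6, adjusted p up to 0.0628), Mpeg1 (without M5, 0.0621), Tgfbi (without M1, M2, M5 or M6, up to 0.0818), Clec4a3 (without any culture but M3, up to 0.232) and Pxdc1 (without any culture but M1, up to 0.197). With no filter on dim probe sets none of the 35 named genes past the test passed, and Chil3 came nearest (adjusted p = 0.074). Clec4a3 and Pxdc1 were also lost with no floor, with no intensity trend and with the labelling batch as a block, Pxdc1 with the mean signal above the 60th percentile, and Mpeg1 with the floor at the 50th percentile.

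The genes that rose were fewer. Gcsam, a signalling adaptor of germinal centre lymphocytes (chromosome 16), had a log2 signal of 9.17 ± 1.04 in the precursors and 12.45 ± 0.13 in the mature cultures (SD, n = 3), a 9.75-fold rise (adjusted p = 0.00858, limma). Smpx, known from striated muscle (chromosome X), had a log2 signal of 8.06 ± 0.19 and 11.03 ± 0.44 in the same order, a 7.81-fold rise (adjusted p = 0.00464, limma). Stum on chip B (chromosome 1) rose 12.5-fold, from a log2 signal of 8.55 ± 0.10 to 12.19 ± 0.28 (adjusted p = 0.00244, limma). Hbb-y, an embryonic globin gene, rose 15.1-fold and 15.5-fold in 2 probe sets. Rgs13, a regulator of G protein signalling, rose 16.5-fold on chip B, as did the set named for the T cell receptor segment Trav6-3. The folds of Smpx, Stum, Rgs13 and Trav6-3 depend on the floor, at which 2 of the 3 precursor cultures lay, and that of Hbb-y does with 1 such culture. Over the alternatives the log2 difference of Smpx ran from 1.84 to 4.16 and that of Stum from 2.44 to 4.15, with 3.20 to 4.73 for Rgs13, 3.20 to 4.61 for Trav6-3 and 3.18 to 4.80 for Hbb-y. Ryr3, a calcium release channel gene, rose 4.80-fold, Tesc, which codes for a calcium-binding protein, rose 3.22-fold, and Jun, a subunit of the AP-1 transcription factor, rose 2.73-fold. A further set of Jun rose 5.10-fold. Ryk, a receptor of the Wnt pathway, was at the floor in the 3 precursor cultures and was at least 4.65-fold higher in the mature cultures (log2 difference 0.98 to 3.29 over the alternatives), while its chip B set had a difference of -0.13 ± 0.41 (log2, SE) and did not pass. In each set called, all 3 mature cultures lay above all 3 precursor cultures, which the rule for named genes required of the sets it took. The signal of Hbb-y spread widely among the mature cultures, with 14930 in M2, 1673 in M4 and 7211 in M6. Among the genes that rose, Gcsam and Smpx passed with each of the 6 cultures left out in turn. With no floor Smpx, Rgs13, Trav6-3 and Ryk were lost, and with the floor at the 50th percentile Hbb-y and Ryk were. The labelling batch as a block ended the calls of Hbb-y, Rgs13, Ryr3, Tesc and Ryk, the station as a block that of Ryk, no intensity trend those of Hbb-y, Rgs13, Tesc and Trav6-3, and array weights those of Hbb-y and Rgs13. Rgs13 was also lost under 75th percentile scaling and with the mean signal above the 60th percentile, a filter that left out Smpx and Ryk. Stum was lost without M6 (adjusted p = 0.057), Trav6-3 without M2, M4 or M5 (up to 0.138), Hbb-y without M2, M3, M5 or M6 (up to 0.139) and Ryr3 without M2, M3, M5 or M6 (up to 0.1). Jun was lost without any culture but M6 (up to 0.125), Rgs13 (up to 0.232) and Tesc (up to 0.132) without any but M1, and Ryk without any of the 6 (up to 0.177).

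**Figure D1:**
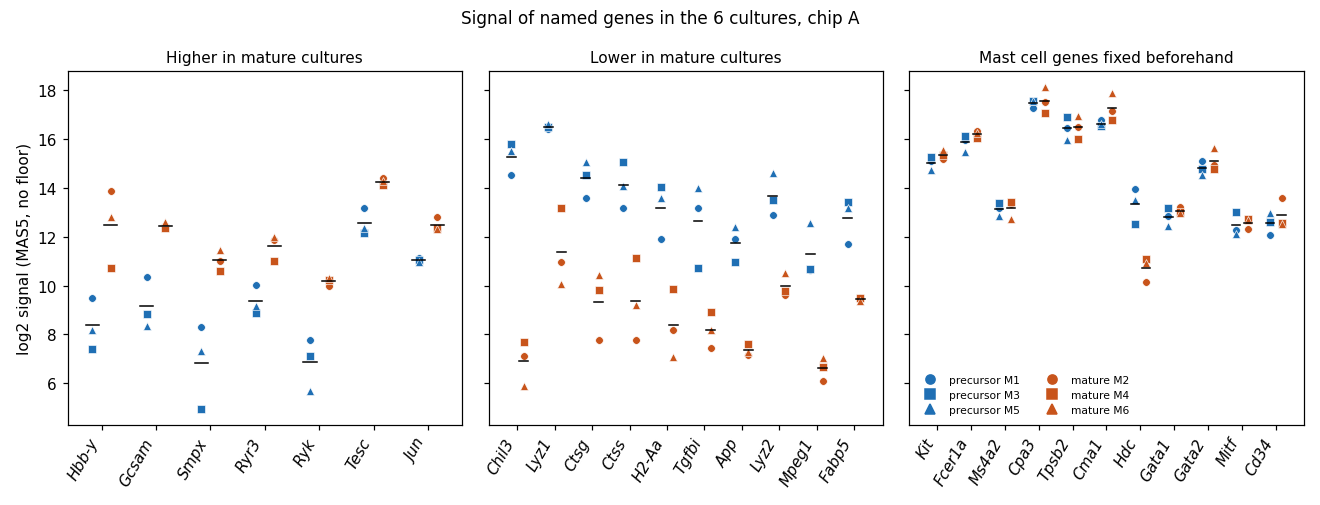
Log2 MAS5 signal, before any floor, of named genes in each of the 6 cultures on chip A; each point is 1 culture, blue for precursors and orange for mature cultures, and the black bars are group means. Chil3 was at least 159.9-fold lower in the mature cultures and Gcsam 9.75-fold higher, while Kit, Fcer1a and Cpa3 did not pass the test.

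Genes that define mast cells were bright at both stages. Kit, the receptor for stem cell factor, had a log2 signal of 15.03 ± 0.26 in the precursors and 15.36 ± 0.18 in the mature cultures (SD, n = 3), a difference of 0.33 ± 0.22 (log2, SE; adjusted p = 0.855, limma). The chains of the IgE receptor gave differences of 0.34 ± 0.23 for Fcer1a (adjusted p = 0.851, limma) and 0.033 ± 0.26 for Ms4a2 (0.991). The granule proteases gave 0.090 ± 0.26 for Cpa3 (adjusted p = 0.977, limma), 0.051 ± 0.30 for Tpsb2 (0.988) and 0.64 ± 0.26 for Cma1 (0.678). Cd34, a sialomucin of progenitors and mast cells, gave 0.33 ± 0.34 (0.915). The transcription factors gave 0.25 ± 0.25 for Gata1, 0.29 ± 0.27 for Gata2 and 0.11 ± 0.29 for Mitf. A further set of Kit had a signal of 1183 to 4263 in the precursors and 3172 to 6133 in the mature cultures. Further sets of Ms4a2 (chip B, 298600 to 324400 and 320000 to 428300), Tpsb2 (1364 to 3368 and 1772 to 2472) and Gata2 (3188 to 7240 and 5724 to 6180) overlapped likewise. None of these genes passed. In simulated data a log2 change of 1 was recovered in 0 of 200 sets, so not passing does not by itself exclude a change of that size. The simulated sets were picked at random. How large a change stays open for each set read here is given by its own difference and SE. The Mcpt4 set was too dim to be tested. Hdc, which makes histamine (chromosome 2), fell 6.13-fold, from a log2 signal of 13.32 ± 0.72 to 10.70 ± 0.51 (SD, n = 3; adjusted p = 0.0134, limma), and its call was lost without M2 or M5 (up to 0.0621). Basophil markers had a list median of -0.46, with 0 of 7 past the test over all genes. Which cells gave the Hdc signal was not tested.

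The 7 lists on mast cells held few changed genes. Of 14 measured granule proteases and amines, 0 rose, 2 fell (Ctsg and Hdc) and 12 did not pass, with the same 2 past the test adjusted over the list alone (list test adjusted p = 0.351, limma). Of 30 measured surface receptors and IgE signalling genes, 0 rose and 0 fell, also adjusted over the list alone, with Csf2rb2 at a difference of 0.18 and Fcer1a at 0.34 (list test adjusted p = 0.933). Of 33 haematopoietic and mast cell transcription factors, 0 rose and 0 fell (0.612). None of 24 genes of heparin and chondroitin sulphate synthesis passed, with Srgn at 0.14 and Chsy1 at 0.15 (0.933). None of 12 eicosanoid synthesis genes passed, with Alox5 at -0.11 and Alox5ap at 0.27 (0.933), and adjusted over the list alone 1 gene fell, Mgst1 (-1.96). None of 31 secretory granule exocytosis genes passed, with Vamp3 at 0.052 and Hps1 at 0.088 (0.758), and adjusted over the list alone Syt9 rose (1.49) and Vamp4 fell (-1.36). None of 15 cytokines and chemokines passed, with Osm at -0.057 and Ccl6 at -2.81 (0.0566), and adjusted over the list alone 1 gene fell, Ccl6. This list passed as lower without M2 (adjusted p = 0.000747) or M5 (0.0398), and Ccl6 passed without M6 (0.0353). The list also passed with the mean signal above the 60th percentile (0.0275), sex as a block (0.0286) or the station as a block (0.0412). In camera with an estimated correlation and all cultures its adjusted p was 0.724. At an unadjusted p under 0.05, 763 sets passed on each chip over all genes. None of 27 stem and progenitor cell genes passed, over all genes or adjusted over the list alone, with Ptprc at -0.006 and Angpt1 at 0.38 (0.933). The camera test and the chip A list median pointed opposite ways in the lists of granule proteases (median 0.051), surface receptors (0.071) and heparin synthesis (0.014), each tested as lower.

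Markers of other myeloid cells were lower in the mature cultures, and those of macrophages gave the lowest p of all lists tested. Of 18 measured monocyte and macrophage markers, 0 rose, 7 fell and 11 did not pass, and 15 fell adjusted over the list alone. The 7 were Lyz1, Lyz2, Mpeg1, Csf1r, the receptor for the macrophage growth factor (8.33-fold, adjusted p = 0.00901, limma), the lectin receptor Clec7a (4.36-fold), the scavenger receptor Cd68 (a log2 difference of -2.07) and Adgre1, the F4/80 antigen (3.21-fold). Of 3 sets of Csf1r only this one passed, and the others had -2.08 and -0.27. It passed with each culture left out in turn, while Clec7a was lost without M2, M3, M4 or M5 (adjusted p up to 0.0861), Cd68 without M1, M2, M4 or M5 (up to 0.142) and Adgre1 without any culture but M3 (up to 0.142). These 3 were also lost with the labelling batch as a block (adjusted p = 0.0501, 0.0596 and 0.0628), and Adgre1 under both other scalings and with no intensity trend. The list median was -2.04 (log2), and the list passed the camera test (adjusted p = 5.11e-23, and adjusted p = 0.132 with an estimated correlation). Of 14 neutrophil and granulocyte precursor markers, 0 rose, 2 fell (Chil3 and Anxa1, the latter 7.66-fold) and 12 did not pass, and 5 fell adjusted over the list alone (median -1.49; adjusted p = 5.96e-10, and adjusted p = 0.251 with an estimated correlation). On chip A, where the list was tested, its median of -1.65 became -0.89 without M5 and -2.57 without M3. In M3 the level of this list (-0.74, log2 relative to each gene's mean) lay below that of the mature culture M6 (-0.48). The call of Anxa1 was lost without M1, M2, M5 or M6 (adjusted p up to 0.0818). Of 15 dendritic cell and MHC class II genes, 0 rose, 2 fell (H2-Aa and H2-Eb1, the latter 3.83-fold) and 13 did not pass, and 4 fell adjusted over the list alone (median -0.15; adjusted p = 0.000564, and adjusted p = 0.144 with an estimated correlation). The chip A median of this list, -0.27, became -0.081 without M2, -0.069 without M3 and -0.43 without M6, and on chip B the list had a median of 0.014 and did not pass (adjusted p = 0.733). H2-Eb1 was lost without M2, M3, M4 or M5 (up to 0.0871). Of 7 basophil markers, 0 rose, 0 fell and 7 did not pass, with Cd200r3 at -1.09 and Cd69 at 0.56, and 3 fell adjusted over the list alone (median -0.46, and on chip A -0.46 or -0.73 without M3; adjusted p = 0.00558, and adjusted p = 0.234 with an estimated correlation). Of 11 bone marrow stromal markers, 0 rose, 1 fell (Igfbp4, 4.26-fold) and 10 did not pass, with Sparc at 0.33 and Fn1 at -1.30, and 3 fell adjusted over the list alone (median -0.29; adjusted p = 0.00222, and adjusted p = 0.384 with an estimated correlation). Of 5 sets of Igfbp4, 3 fell, the others of these 6.21-fold and 6.90-fold, and 2 did not pass (-0.56 and -1.18). The call of Igfbp4 was lost without M2, M3, M5 or M6 (up to 0.096) and with the labelling batch as a block (0.0561). With no filter on dim sets the stromal list had a median of 0 and did not pass (adjusted p = 0.227). The only eosinophil marker measured, Epx, had a difference of -1.33 and did not pass.

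Lysosomal and adhesion genes were also lower as lists in the mature cultures, beside a macrophage list median of -2.04. Of 35 lysosomal genes, 0 rose, 4 fell and 31 did not pass, and 7 fell adjusted over the list alone (median -0.27; adjusted p = 9.28e-07, and adjusted p = 0.234 with an estimated correlation). The chip A median of this list, -0.25, became -0.13 without M4, and the list did not pass on chip B (adjusted p = 0.0632). The 4 were the cathepsins Ctss, Ctsl (9.58-fold), Ctsh (6.95-fold) and Ctsz (3.50-fold), the last lost without any culture but M1 (up to 0.164). A set of Ctsh on chip B (-3.23, adjusted p = 0.0675) and 2 further sets of Ctsz (-1.64 and -1.32) did not pass. The call of Ctsz held in 3 of the 12 alternatives that kept all cultures, those with the floor at the 50th percentile, with sex as a block and with array weights. Of 31 integrins, sialomucins and adhesion genes, 0 rose, 1 fell and 30 did not pass, and adjusted over the list alone 10 fell and 1 rose (median -0.35; adjusted p = 8.1e-08, and adjusted p = 0.132 with an estimated correlation). The gene that fell was Itgb2, a leukocyte integrin chain (4.01-fold), whose call was lost without M1 or M5 (up to 0.0621). The chip A median of this list, -0.34, became -0.53 without M6. The platelet integrin genes Itga2b and Itgb3 had differences of 0.44 and -0.46. Ribosomal protein genes were lower as a list: of 39, 0 rose, 0 fell and 39 did not pass, also adjusted over the list alone, with a median of -0.39, Rps28 at 0.17 and Rps3 at -0.12 (adjusted p = 5.24e-08, and adjusted p = 0.307 with an estimated correlation). A sign of RNA quality moved with the stages and so with all of these groups. The ratio of 3' to 5' actin signal on chip A was 6.34, 7.04 and 4.81 in M1, M3 and M5, and 9.73, 10.07 and 9.84 in M2, M4 and M6. On chip B it was 5.61, 7.25 and 4.87, and 8.66, 9.12 and 10.81. The same ratio of Gapdh overlapped between the stages on chip A, at 9.11, 13.46 and 9.39 in the precursors and 19.31, 12.82 and 14.33 in the mature cultures. On chip B it did not, at 9.44, 13.69 and 11.96 against 22.05, 16.84 and 19.95.

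The lists that were higher in the mature cultures held 1 changed gene, beside the 3' to 5' actin ratio of 9.73 to 10.07 in the mature and 4.81 to 7.04 in the precursor cultures and the macrophage list median of -2.04. Of 22 immediate early and heat shock genes, 1 rose (Jun), 0 fell and 21 did not pass, with Ier3 at 0.62 and Hspa8 at 0.001. Adjusted over the list alone 4 rose, Egr1 (2.00), Fos (1.87), Jun (1.45) and Ier2 (0.93), all genes of the early response (list median 0.27; adjusted p = 0.00165, and adjusted p = 0.384 with an estimated correlation). Without M2 the list no longer passed (adjusted p = 0.121), and its chip A median of 0.29 became 0.12, against 0.57 without M6. Egr1 passed over all genes with array weights (0.0306). Of 22 genes of cholesterol synthesis and uptake, 0 rose and 0 fell, also adjusted over the list alone, while 20 had a higher value, with Hmgcs1 at 1.02 and Insig1 at 1.03 (median 0.47; adjusted p = 0.000578, and adjusted p = 0.684 with an estimated correlation). Without M3 this list no longer passed (chip A median 0.074, adjusted p = 0.727), and its median was -0.23 within the cultures of low spike ratio, against 0.85 within those of high spike ratio. Of 28 glycolysis and hypoxia-responsive genes, 0 rose and 0 fell, also adjusted over the list alone, with Pgk1 at 0.16 and Ldha at 0.28 (median 0.18; adjusted p = 0.0453, and adjusted p = 0.724 with an estimated correlation). This list was lost without M2, M3 or M4 (up to 0.748), its chip A median ran from -0.095 without M2 to 0.35 without M6, and its median was -0.062 on fluidics station 2 and -0.13 within the cultures of low spike ratio. It was also lost under 75th percentile scaling (adjusted p = 0.0584), with no filter on dim sets (0.139), with no intensity trend (0.0663), with the mean of all kept sets of a gene (0.0517) and on chip B (0.966).

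No cell cycle gene passed the test. Of 41 DNA replication and G1/S genes, 0 rose and 0 fell, also adjusted over the list alone, with Pcna at -0.71 and Mcm7 at -0.21 (median -0.21; adjusted p = 0.0453, and adjusted p = 0.87 with an estimated correlation). The list was lost without M5 (adjusted p = 0.973) or M6 (0.174), where its chip A median of -0.19 turned to 0.051 and 0.087, and had a median of 0.25 on fluidics station 1 and 0.036 within the cultures of high spike ratio. It was also lost under 75th percentile scaling (0.0584), with no filter on dim sets (0.169), the mean signal above the 60th percentile (0.05), no intensity trend (0.0562), array weights (0.817), the labelling batch as a block (0.609) and on chip B (0.966). None of 45 mitosis and G2/M genes passed, with Cdca8 at -0.78 and Cks2 at 0.44 (list test adjusted p = 0.0522, limma), none of 23 cell cycle inhibitors and p53 targets, with Rprm at 0.77 and Cdkn1a at 0.37 (0.319), and none of 21 regulators of apoptosis and survival, with Pim1 at 0.61 and Cish at 0.14 (0.235). Adjusted over the list alone, 1 of these genes fell, Cdkn2b (-1.35). The mitosis list passed as lower without M2 (adjusted p = 5.63e-05), M3 (2.14e-05) or M4 (0.000569), and as higher without M6 (0.0154). It passed as lower with quantile normalization (0.0354), no floor (0.0424), the mean signal above the 60th percentile (0.0264), sex as a block (0.0308) or the station as a block (0.0462), and the apoptosis list passed as higher without M3 (0.0425). In camera with an estimated correlation the adjusted p was 0.87 for mitosis and 0.846 for apoptosis, with all cultures.

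No gene passed in the remaining lists, where 763 sets passed on each chip at an unadjusted p under 0.05 over all genes. They were 51 oxidative phosphorylation genes (Uqcrb 0.28, Ndufa1 0.41; list test adjusted p = 0.395, limma), 21 interferon-stimulated genes (Ifi35 -0.26, Ddx58 -0.16; 0.481) and 31 genes of the unfolded protein response and amino acid stress (Xbp1 -0.052, Calr 0.083; 0.737). The others were 7 erythroid markers (Tfrc -0.61, Car2 -0.18; 0.933), 11 megakaryocyte and platelet markers (F2r 0.48, Itga2b 0.44; 0.496) and 6 lymphoid markers, too few on chip A for a list test (Cd8a 0.38, Pax5 0.58). Adjusted over the list alone, Pdia4 of the unfolded protein response fell (-1.56), and of the platelet markers Pf4 fell (-3.79) and Gp5 rose (1.20). Pf4 passed over all genes without M3 (adjusted p = 0.000569) and with sex as a block (0.0491), and Pdia4 with the station as a block (0.0477). The oxidative phosphorylation list passed as lower without M2 (0.0134) or M3 (0.0323), and the unfolded protein response list as lower without M2 (0.0353) and as higher without M6 (0.0216). In camera with an estimated correlation and all cultures both lists had an adjusted p of 0.958. The median and the camera test pointed opposite ways for the erythroid markers (median 0.21, tested as lower) and the unfolded protein response (0.036, tested as lower). In all, 12 of 28 lists passed, 9 lower and 3 higher, and none did with an estimated correlation, where 5 lists had an unadjusted p under 0.05, or with fry, where 7 had.

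**Figure D2:**
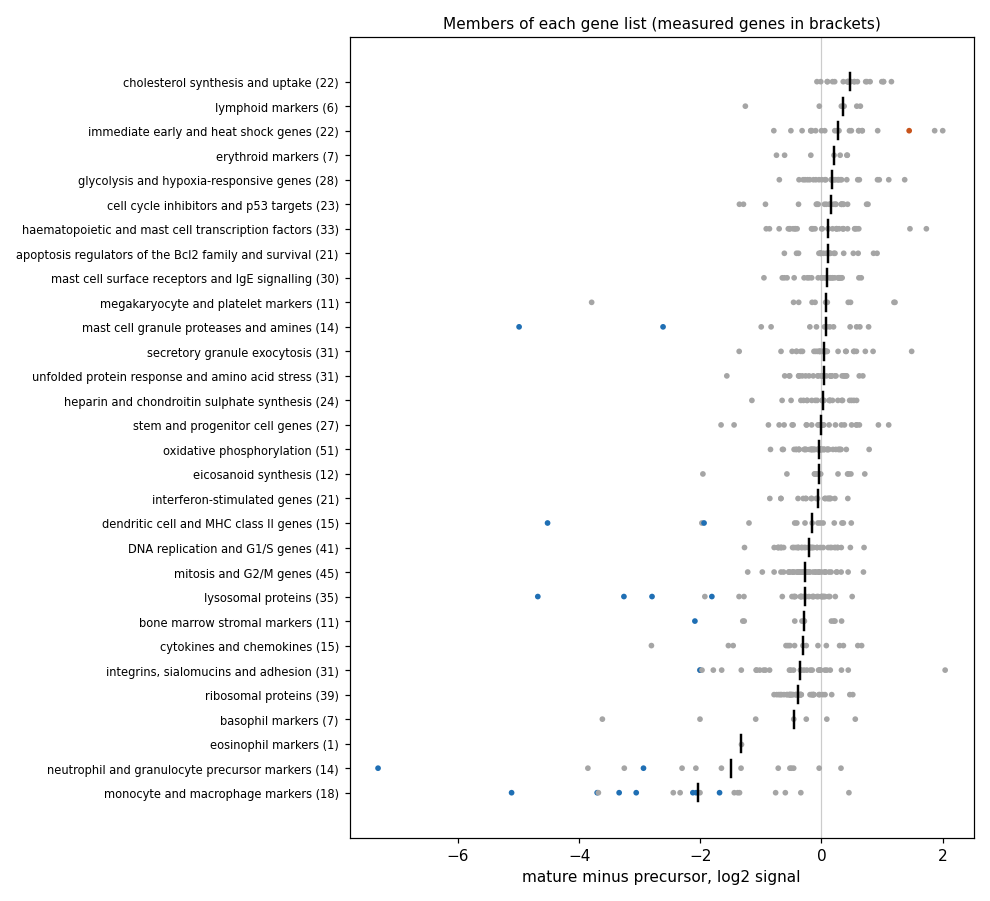
Difference between mature and precursor cultures (log2 signal, mature minus precursor) of each measured member of the gene lists, 1 point per gene; orange points rose, blue points fell, grey points did not pass the test, and black ticks are list medians. The macrophage list has the lowest median among the lists tested, -2.04, and the cholesterol list lies at 0.47.

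The scanner records gave 1 chip lot and 1 scan day per chip, and 2 fluidics stations, with M1 and M2 on station 1 and the others on station 2. The ratio of 5' to 3' signal of the poly-A spike controls on chip A split the cultures another way, between 0.0878 and 0.103 in M1, M4 and M6 and between 0.184 and 0.23 in M2, M3 and M5, which was read as a labelling batch. With the station as a block, 62 sets of chip A changed, 56 of them among the 61, and 9 of chip B, 8 of them among the 11. With the labelling batch as a block there were 39, with 38 among the 61, and 6, all among the 11. Of the 35 named genes past the test, 2 were lost with the station (Ctsz and Ryk) and 12 with the labelling batch as a block. The median of the macrophage list was -1.93 on each station, -1.37 within the low spike ratio and -2.66 within the high. The granulocyte list had medians of -2.33, -1.36, -1.57 and -1.84 in the same order, the lysosomal list -0.40, -0.24, -0.32 and -0.22, and the adhesion list -0.94, -0.23, -0.54 and -0.63. The MHC class II list had -0.32, -0.18, -0.46 and -0.44, the stromal list -0.64, -0.27, -0.39 and -0.53, the basophil list -1.18, -0.70, -1.07 and -0.69, and the ribosomal list -0.084, -0.41, -0.31 and -0.36. The early response and heat shock list had 0.99, 0.31, 0.26 and 0.63.

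The first principal component of chip A carried 37.5% of the variance and set M5 (-46.4) and M6 (54.8) furthest apart, with the other 4 cultures between -9.2 and 7.3. The 3 precursor cultures lay between -46.4 and -8.5 and the 3 mature cultures between 2.0 and 54.8. On chip B they lay between -45.4 and -11.6 and between 4.9 and 59.3. The second component of chip A carried 22.5%. M6 had the lowest mean correlation with the other arrays, r = 0.868 across genes, against 0.885 for M5 and 0.909 to 0.913 for the others, and genes are not independent replicates. M6 also differed in the RNA concentration on its label, 1.0 ug/ul against 1.5 to 2.0, in the signal of the hybridization spikes, 48011 against 18045 to 25480, and in its median signal, 695 against 536 to 592. Without M6, 48 sets of chip A changed, 37 of them among the 61, and 3 sets of chip B, all among the 11.

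Sex-linked genes were read as a check of the labels and had no part in the stage comparison, where Xist (0.11) and Eif2s3y (0.71) did not pass. Xist, the RNA of the inactive X chromosome, had a signal of 37970 in M1 and 43300 in M6, the cultures labelled female, and 687 to 926 in the 4 cultures labelled male. Eif2s3y, a gene of the Y chromosome, had a signal of 17.7 in M1 and 1175 to 3134 in the male cultures. M6, labelled female, had 1105. For a set of Kdm5d the signal was 147 in M1, 535 in M6 and 319 to 786 in the male cultures, and for a set of Uty on chip A it was 217, 591 and 373 to 474. A further chip A set of Kdm5d had 416 in M1 and 78.8 in M6, and a further one of Uty 260.5 and 232.9. Neither of these set M1 below all male cultures. Of 20 Y-linked probe sets on both chips, 7 set M1 below all 4 male cultures, and in 5 of these at least 1 male culture lay above the floor. In each of the 5 M6 lay above M1, which noise alone would often give in sets picked for a low M1. Ddx3y had no named probe set.

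**Figure D3:**
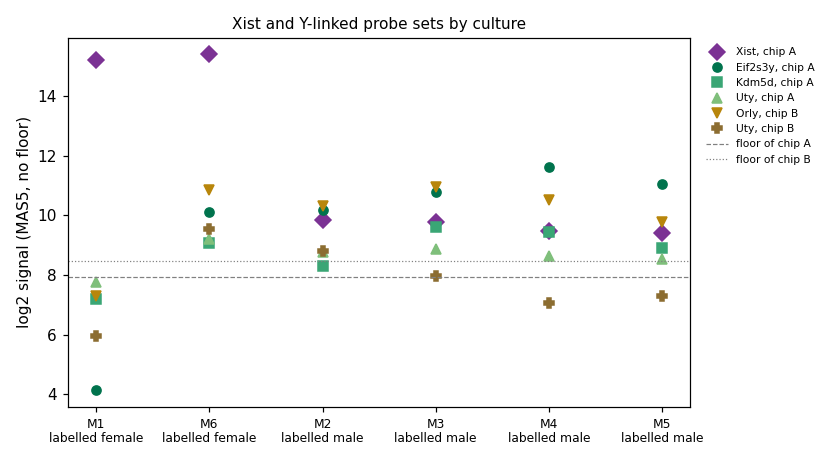
Log2 MAS5 signal, before any floor, of Xist and of the 5 Y-linked probe sets that set M1 below the 4 male cultures with at least 1 of these above the floor, by culture with its labelled sex; each point is 1 probe set and the grey lines are the floors of the 2 chips. M6 has both a Xist signal of 43300 and an Eif2s3y signal of 1105.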

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

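All tests in this part were chosen after the results by sex were seen. Each list below was picked out by a test of the difference between the stage effect in the male cultures (M2 and M4 against M3 and M5) and in the female cultures (M6 against M1). The camera test with the interaction of stage and sex called 7 of 28 lists at a preset correlation and 0 with an estimated one, where every list had an adjusted p of at least 0.819 and 0 had an unadjusted p under 0.05. In the fits per probe set the interaction called 0 sets on chip A (limma, 875 at an unadjusted p under 0.05) and 0 on chip B (679). The female stage effect rests on 1 culture per stage, and M6 also carried Y-linked signal, so that sex and the single cultures cannot be separated in it.

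The mitosis and G2/M list had a stage median (log2, mature minus precursor) of -1.12 in the female and 0.18 in the male cultures, a difference of 1.31 (adjusted p = 9.64e-13, limma). The DNA replication and G1/S list had -0.68 and -0.017 (difference 0.66, adjusted p = 4.87e-06). The cholesterol list had -0.31 and 0.80 (difference 1.11, 0.00032), and the glycolysis and hypoxia list -0.26 and 0.48 (difference 0.74, 0.00032). The cytokine and chemokine list had -0.62 and -0.064 (difference 0.56, 2.68e-05), the oxidative phosphorylation list -0.31 and 0.066 (difference 0.37, 0.0035), and the unfolded protein response list -0.24 and 0.14 (difference 0.38, 0.0011).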

How the results depend on the processing

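The blocks for fluidics station and labelling batch and the filter that leaves out only sets at the floor on all 6 arrays were chosen after seeing the data; the other alternatives were planned. The block for chip lot or scan day was not run, because each chip has 1 lot and 1 day. The 61 changed sets on chip A became 1 with no filter on dim sets, where limma gave 1231 sets an unadjusted p under 0.05, 1 with only the sets at the floor on all 6 arrays left out, 39 with labelling batch as a block (38 of them among the 61), and 18 at an adjusted p under 0.01, a stricter threshold. Leaving out each culture in turn gave 21 to 59. The 11 on chip B became 0 with no filter (limma, 1227 at an unadjusted p under 0.05), 3 with only sets at the floor on all 6 arrays left out, 4 with no floor, 17 with the floor at the 50th percentile, 6 with the mean above the 60th percentile, 17 with sex as a block, 3 with no intensity trend, 7 with array weights, 6 with labelling batch as a block, 21 with both chips adjusted together and 4 at an adjusted p under 0.01, and 3 to 11 with 1 culture left out. The 12 lists past the test became 0 with an estimated correlation (5 at an unadjusted p under 0.05), 0 with fry (7) and 1 on chip B, where 13 lists were tested, and 12 to 14 with 1 culture left out. The DNA replication list, median -0.19 on chip A, turned sign with array weights (0.043) and without M5 (0.051) or M6, and the glycolysis list did in the chip B test (-0.058) and without M2 (-0.095). The MHC class II list went from -0.27 to 0.014 in the chip B test, and the stromal list from -0.31 to 0 with no filter, where it did not pass. For DNA replication on chip B the median (-0.039) kept its sign while camera pointed upward (adjusted p = 0.966). With 1 culture left out the medians ran from -0.48 to 0.087 for DNA replication, -0.54 to 0.14 for mitosis and -0.12 to 0.19 for the unfolded protein response, each highest without M6. Apart from the stricter threshold and the fewer arrays, the cause was not tested. The 35 named genes past the test kept their direction in all 627 values under these alternatives and their side of the threshold in 465, and 13 of the 35 passed with each culture left out in turn. The groups of each called set did not overlap, so its direction could not reverse with 1 culture left out, another floor or array weights. Other filters and no intensity trend leave the difference itself unchanged. The kept direction was thus largely fixed beforehand. Signal near the floor limits the folds, and a log2 change of 1 was called in 0 of 200 simulated sets on each chip.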

Other observations

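The tests on labelling batch and station, on fewer macrophages, on the sex label, on a mixture of cells and on heat shock genes were chosen after the results they measure were seen; the tests on scaling, on raised background and on other splits were not.

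Among the precursor cultures M3 had the lowest signal in 12 of 14 granulocyte and 5 of 7 basophil markers, a count that was not tested. Chil3 was highest in M3 (23410 in M1, 56620 in M3 and 46430 in M5), and Cd200r3 had 15550, 16070 and 17770. Myeloperoxidase (Mpo) had a signal of 18910 in M1, 614 in M3 and 39340 in M5, the neutrophil granule gene Ngp 29860, 601 and 60670, and the basophil protease gene Mcpt8 41660, 1502 and 24180. In the mature cultures Mpo lay between 670 and 938. Cholesterol genes were lowest in M3, with a list median of -1.11 (log2, relative to each gene's mean over the cultures) against -0.093 to 0.38 in the other 5. The mitosis list was lowest in M6 (-0.99) and highest in M5 (0.75), and the DNA replication list likewise (-0.70 and 0.68). These genes were picked after their values were seen.

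Macrophage markers were lower in the mature cultures. Scaling is argued against, since the list median stayed at or below -2.00 under 75th percentile scaling and quantile normalization. A shift between stations would cancel, since station 1 held 1 culture of each stage and station 2 held 2 of each. The medians of -1.37 within the low and -2.66 within the high spike ratio argue against labelling batch as the whole cause. However, 1 stage had only 1 culture in each spike batch. Within the low spike ratio the lowest of 10000 random lists reached -0.51, but random genes do not measure the spread among cultures. A candidate explanation is fewer macrophages and monocytes in the mature cultures, which the labels name as possible other cells. Of 18 measured markers, 17 had a lower value. Lyz2 had 7646 to 24640 in the precursors and 772.5 to 1462 in the mature cultures, and Csf1r 6402 to 24270 and 1408 to 1756. These lower values restate the pattern, and the labels give the same purity, about 80%, for both stages. Of the 18 markers, 1 is in another list and 9 stayed above the chip median in all 3 mature cultures. A change of these genes within the mast cell lineage would give the same values and stays open, as does RNA quality, since the actin ratio moved with the stages.

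M6 is labelled female, yet Xist and Y-linked signal occurred together in it. A wrong label alone is argued against, because its Xist signal was 46.8 times the highest of the male cultures. For Eif2s3y (1105 in M6) a raised background is too. Of the chip A sets under the floor in M1, 1.16% (77 of 6619) lay above 4 times the floor in M6. Kdm5d (535) and Uty (591) on chip A lay under that cut in M6, and chip B was not tested. A smaller rise of the background stays open for these sets. A mixture of female and male cells or RNA may account for both signals. Of the Y-linked sets that set M1 below all male cultures, 5 had at least 1 of these above the floor. In 4 of the 5, M6 lay at or above the lowest male culture (6 of 7 sets if dim ones count). This count says little, since noise alone would often put M6 there in sets picked for a low M1. The exception, Eif2s3y, had 1105 in M6, 1175 in the lowest male culture and 17.7 in M1. A mixture would lower Xist. Its signal in M6 was 1.14 times that of M1 in the set tested. In further sets it was 9572 in M6 against 10370 in M1, and 449 against 307. No biological explanation was tested.

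Early response genes had a median difference of 0.62 over 15 genes, 12 of them higher in the mature cultures. Only Jun passed over all genes, and the 15 were not tested as a set. The list that holds them did not pass with an estimated correlation (adjusted p = 0.384, camera), with fry (0.455) or without M2 (0.121, camera). Scaling is argued against, since the median was at least 0.60 under 75th percentile scaling and quantile normalization. A shift between fluidics stations would cancel, since station 1 held 1 culture of each stage and station 2 held 2 of each. Each labelling batch held cultures of both stages. With the labelling batch as a block Jun still passed, and so did the list in camera at the preset correlation. The medians of the early response genes were 0.51 within the low and 1.02 within the high spike ratio. However, 1 stage had only 1 culture in each, so a part played by the batch stays open. The lowest of the 4 medians within a batch was 0.33, on station 2. Random lists of 15 genes had an SD of 0.15 there, and 3.71% of them lay as high. Stress at harvest could raise early genes and heat shock genes together, and the 6 heat shock genes had a median of -0.088, with values from -0.50 to 0.49, which leaves it open. A difference between the stages themselves also stays open, untested beyond the comparison.

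The 6 cultures make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 61 changed sets on chip A, where the highest of the other splits gave 0, and 11 on chip B, where the highest gave 0, in limma at an adjusted p under 0.05; 1 split, the real one, reached each count. For the lists past the test the real split gave 12 and the highest of the others 13, that of M1, M2 and M5 against the rest, and 2 splits, the real one included, gave as many as the real one. For 5 of the 12 lists another split gave a lower unadjusted p in camera than the real one: granulocyte (8.23e-12 against 4.26e-11), early response and heat shock (7.62e-07 against 0.000472), cholesterol (5.19e-09 against 0.000145), glycolysis (2.67e-07 against 0.0192) and DNA replication (1.8e-16 against 0.0194). These are all 3 lists called higher and 2 of those called lower.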
